A study of Enchytraeus albidus with 48 samples.

How the data were processed

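The samples were whole-body total RNA extracts of adult *Enchytraeus albidus*, an oligochaete worm, kept 15 to a vessel in 25 g of soil at 20 °C, per the labels' protocols. Soil was unspiked or held cadmium or zinc at the EC50 or EC90 for reproduction, and worms were taken after 2, 4 and 8 days. Per the labels' protocols, 0.5 µg of RNA from each vessel was amplified and labelled with the dye Cy3, and each array carried 1 sample in 1 colour.

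The arrays were read with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. The deposited intensity of each spot, called the processed signal, is on a linear scale, was background-subtracted and detrended by that software and was not normalized between arrays, per the file headers. The value table the authors deposited for the whole series holds intensity values too, and it was compared with the processed signal spot by spot. The largest difference was 0, so it is the same data on the same scale, uncentred, and a separate run on it was not made. Its column medians lay between 54.4 and 297.5. Each array had 15208 spots for 1035 probes, 718 probes with 15 spots and 317 with 14, and 536 control spots that were left out. Arrays lay on 9 slides, of which 3 held 1 array each, with 7 scan days. The files pair probes with clone or contig names only. The 29 gene lists and the gene names fixed for this study could therefore not be matched, and 0 lists were tested.

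From the processed signal the following was computed. Spots marked as outliers by the scanner software (2.43% to 7.11% per array) were left out and saturated spots (198 to 1108 per array) were kept. Log2 signals were averaged over the spots of a probe, and the 75th percentile over probes was subtracted in each array. A probe counted as well above background on an array when over 0.5 of its spots did. Probes well above background on every array of at least 1 of the 15 groups were kept, which left 909 and removed 126. Where a probe was not well above background on any array of a group, only a bound is given: the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the lowest signal well above background and the probe's own signal. Likewise, for a probe saturated on every array of a group only the bound is given, with saturated spots at their value.

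Replicates were compared before averaging. Over 404 probes with a log2 signal between 7 and 15, 5 of the 54 pairs of arrays within groups had an SD of log2 differences below the median of the spike-in probes (0.156), with correlations of 0.99875 to 0.9995 and 0 probes over 2-fold apart. The other pairs had at least 22 such probes. These 5 pairs were averaged and counted as 1 sample each. The tests had been written for 48 separate arrays, and that fit was kept as an alternative.

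All 43 samples entered one limma fit with a mean for each of the 15 groups (28 residual degrees of freedom, 4.01 prior degrees of freedom, median residual SD 0.537). Contrasts compared each exposed group with the control of its day, cadmium with zinc on each day, EC90 with EC50, and the responses of day 8 with those of day 2. The controls of the 3 days were compared by an F-test. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. The tests, sample groups, naming rule and most of the settings below were fixed before the data were examined. As no gene names are given, the rule takes at most 2 probes that rose and 2 that fell per comparison, those with the largest change past the threshold, and for the exposures only probes whose exposed arrays all lie on the same side of all controls. For the differences between metals, concentrations and days only size counts. Other probes are said to be chosen after their values were seen.

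The fit was tested on simulated data with 200 changed probes among 909. For the Cd EC50 of day 2 it found 40% of 2-fold, 86% of 4-fold and 100% of 16-fold changes, and for the Zn EC90 of day 8 it found 24%, 80% and 96%. The simulated values varied independently between probes and held no slide differences. With 200 changed probes the adjusted threshold is also easier to pass than in the exposures, where 0 to 13 were called. These shares may therefore overstate what the real tests could find. Alternatives were quantile normalization, normexp background correction (offset 50, on the median spot and background signals, since the files hold no mean signal), no filter on dim probes, slide as a fixed block, replicate number as a block, array weights, a fit of the compared groups alone, and leaving out each sample in turn. The fit of 48 arrays and one with all spots kept were added after seeing the data. Quantile normalization moved the median difference of all probes by between -0.22 and 0.19 on the log2 scale relative to the 75th percentile. Differences within a slide came from a fit with a mean for each group on each slide, in which an arm of 1 sample takes its spread from the other groups, so no p-value is given for it. The day 2 control pair that lies on different slides is 1 sample assigned in equal parts to both slides in the slide block, and enters the within-slide fit as 1 array per slide. Other splits of the samples, at most 100 per comparison, were refitted in the same way. R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, were used.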

Results

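Gene expression was measured in whole-body RNA of adult *Enchytraeus albidus*, a small oligochaete worm of soils, on 48 one-colour arrays with 1035 probes each. The worms had spent 2, 4 or 8 days in control soil or in soil with cadmium (Cd) or zinc (Zn). Each metal was given at the concentration that lowers reproduction by 50% (EC50) or by 90% (EC90). Per the labels, each array held the RNA of a separate vessel of 15 worms, with 3 vessels for each of the 12 exposed groups and 4 for the controls of each day. Between 67.9% and 89.1% of the 15208 probe spots of an array were well above background, and the 75th percentile of the processed signal lay between 510.2 and 3867. The files pair probes with clone or contig names and with no gene names, so probes are identified by those names: 345 begin with Ealb_Met, 198 with Ealb_Pest, 319 with P and 171 with Contig. Reproduction itself was not analysed here.

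In 5 pairs of arrays of the same group, the SD of the log2 differences over 404 probes was 0.0645 to 0.103. In the other pairs within groups it was 0.542 to 1.31, and for 5 spike-in probes its median between arrays was 0.156. These pairs were control replicates 2 and 4 of day 2, Cd EC50 replicates 1 and 2 of day 4, Zn EC90 replicates 1 and 2 of day 4, Zn EC50 replicates 1 and 2 of day 8 and Zn EC90 replicates 2 and 3 of day 8. The arrays of the day 2 control pair lay on slides 1 and 2, and those of each other pair on 1 slide. Each pair differed by less than that spike-in median, which is over all pairs of arrays. It differed by more than its own spike-in probes did (SD 0.0183 to 0.0689). Each pair was counted as 1 sample, which left 43 samples. The sample size was then 3 for the day 2 control and 2 for Cd EC50 day 4, Zn EC90 day 4, Zn EC50 day 8 and Zn EC90 day 8. All values are log2 processed signals relative to the 75th percentile of the array. The number of arrays limits the precision, and the p-values measure the spread between these samples.

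The first question was which transcripts each metal changed against the control of the same day. After 2 days of cadmium, Contig123 rose from -4.45 ± 0.77 (SD, n = 3) in the controls to -1.03 ± 0.69 (SD, n = 3) at the EC50 and 2.42 ± 0.86 (SD, n = 3) at the EC90. These rises were 10.7-fold (log2 3.42, SE 0.41, limma adjusted p = 1.6e-06) and 117-fold (log2 6.87, SE 0.41, limma adjusted p = 2.22e-14). Ealb_Met_P7_E8_T7_2175287 rose 8.61-fold at the EC50 (log2 3.11, SE 0.42, limma adjusted p = 8.69e-06) and 72.8-fold at the EC90 (log2 6.19, SE 0.42, limma adjusted p = 3.4e-13). For both probes every cadmium sample lay above every control sample. Ealb_Met_P6_F11_SP6_2090590, chosen after its values were seen, rose 14-fold at the EC90 (log2 3.80, SE 0.46, limma adjusted p = 5.42e-07). At the EC50 it differed by 0.79 (SE 0.46, limma adjusted p = 0.544). In the controls it was dim, with a mean signal of 5.68, 12 and 13.3 on days 2, 4 and 8. It was well above background on 3 of 4 control arrays each day, so its folds rest partly on readings near background. The probes named here were the 2 called at the EC50 and the 3 called at the EC90 among 909 tested, all higher. The counts were 4 at each concentration with slide as a block, and Contig123 rose by 2.96 and 6.72. Within slide 1 Contig123 was higher by 3.06 (EC50) and 7.01 (EC90), and within slide 2, with 1 exposed sample, by 5.86 (EC90); control sample 2-4 has an array on each slide and serves as a control on both, so the slides are not independent. Without control sample 2-4 the counts became 99 (38 higher, 61 lower) and 107 (30 higher, 77 lower), without Cd EC50 replicate 1 the first became 13, and without Cd EC90 replicate 1 the second became 5.

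After 4 days of cadmium the same 2 probes stood apart. Contig123 went from -3.89 ± 0.29 (SD, n = 4) in the controls to -0.93 ± 0.19 (SD, n = 2) at the EC50 and 2.33 ± 0.16 (SD, n = 3) at the EC90, a rise of 7.73-fold (log2 2.95, SE 0.44, limma adjusted p = 0.000114) and 74.4-fold (log2 6.22, SE 0.39, limma adjusted p = 2.89e-14). Ealb_Met_P7_E8_T7_2175287 rose 83.2-fold at the EC90 (log2 6.38, SE 0.39, limma adjusted p = 2.89e-14). At the EC50 it rose 4-fold (log2 2.00, SE 0.44, limma adjusted p = 0.0377), and its 2 samples read -0.65 and -2.81, both above every control. With slide as a block this EC50 rise was 3.01, a value that rests on the 1 sample on slide 3. Ealb_Met_P6_F11_SP6_2090590 was the remaining call at the EC90, 6.8-fold higher (log2 2.77, SE 0.43, limma adjusted p = 9.18e-05); at the EC50 it differed by 0.14 (SE 0.49, adjusted p = 0.886). The counts were 2 at the EC50 and 3 at the EC90, all higher, and were also 2 and 3 with slide as a block. Contig123 was higher by 2.86 (adjusted p = 0.0303) and 5.99 in that fit, the same as within slide 3, where the EC50 had 1 sample, so its blocked value rests on that sample. The EC50 count was 1 with replicate number as a block and, by limma, 0 in a fit of only the groups compared (210 at an unadjusted p under 0.05 in the fit of all groups), where Contig123 had the same difference and an adjusted p of 0.0792. It was 87 (13 higher, 74 lower) after quantile normalization, 175 without Cd EC50 sample 1-2, 20 without control replicate 1, 24 without replicate 2, and 1 without replicate 3 or replicate 4; without Cd EC50 sample 1-2 the difference of Ealb_Met_P7_E8_T7_2175287 was 0.92 (adjusted p = 0.164).

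After 8 days Contig123 was at -3.61 ± 0.07 (SD, n = 4) in the controls, -0.94 ± 0.25 (SD, n = 3) at the Cd EC50 and 2.43 ± 0.47 (SD, n = 3) at the EC90. The rises were 6.36-fold (log2 2.67, SE 0.39, limma adjusted p = 7.07e-05) and 65.9-fold (log2 6.04, SE 0.39, limma adjusted p = 6.53e-14). Ealb_Met_P7_E8_T7_2175287 rose 5.92-fold (log2 2.57, SE 0.39, limma adjusted p = 9.97e-05) and 77.3-fold (log2 6.27, SE 0.39, limma adjusted p = 6.53e-14). Ealb_Met_P6_F11_SP6_2090590 was 8.27-fold higher at the EC90 (log2 3.05, SE 0.43, limma adjusted p = 1.41e-05), a call lost with slide as a block (2.59, SE 0.72, adjusted p = 0.319). At the EC50 it differed by 0.97 (SE 0.43, adjusted p = 0.639).

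At the EC90 of day 8, 3 probes also fell. Ealb_Met_P2_C10_SP6_2090305 was not well above background in any exposed array and was at least 2.11-fold higher in the controls, of which 3 arrays measured it (limma adjusted p = 0.000462; 0.00377 with slide as a block). Ealb_Met_P1_C3_SP6_2090161 was likewise at least 2.3-fold higher in the controls (limma adjusted p = 0.0452; 0.912 with slide as a block). Contig51, chosen after its values were seen, fell by 3.06 (SE 0.76, limma adjusted p = 0.0452), from -0.15 ± 1.81 (SD, n = 4) to -3.21 ± 1.67 (SD, n = 3); with slide as a block the difference was as large and its error wider (-3.08, SE 0.95, adjusted p = 0.513). With normexp background correction the adjusted p of both Ealb_Met probes was 0.992, and in a fit of only the groups compared it was 0.503 for Ealb_Met_P2_C10_SP6_2090305 and 0.0668 for Ealb_Met_P1_C3_SP6_2090161. The call of the latter was also lost without control replicate 1 (adjusted p = 0.116), 2 (0.108), 3 (0.0683) or 4 (0.201) or without Cd EC90 replicate 1 (0.0988) or 3 (0.478). Across the alternatives that keep all samples, the log2 difference ran from -2.65 to -0.353 for Ealb_Met_P2_C10_SP6_2090305. For Ealb_Met_P1_C3_SP6_2090161 it ran from -2.57 to -0.254. The bounds of both probes therefore hold only for the processing first given. The counts were 2 at the EC50 and 6 at the EC90; with slide as a block they were 1 and 3, Contig123 at the EC50 being lost (2.56, SE 0.56, adjusted p = 0.0552). Slide 5 held 1 control, on which the within-slide differences of Contig123 (2.56 and 5.72) and the blocked values rest, and the spread comes from the other groups. Without control replicate 3 the EC50 count was 11.

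**Figure D1:**
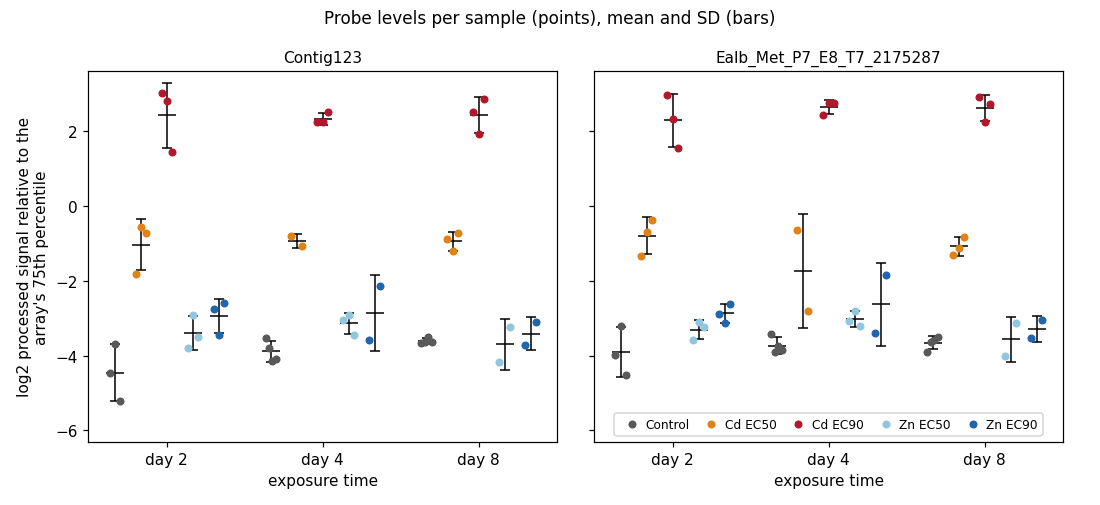
Log2 processed signal of Contig123 (left) and Ealb_Met_P7_E8_T7_2175287 (right) relative to the 75th percentile of the array, by exposure time and treatment; points are samples, and bars show the mean and the SD. Contig123 averaged 2.42, 2.33 and 2.43 at the Cd EC90 on days 2, 4 and 8, and -4.45, -3.89 and -3.61 in the controls.

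After 2 days at the zinc EC90, P1_F7_T7_1328858 rose from -2.27 ± 1.25 (SD, n = 3) to 0.37 ± 0.85 (SD, n = 3), a difference of 2.64 (SE 0.70, limma adjusted p = 0.0447). P5_F2_T7_1329804 rose from -5.29 ± 0.57 (SD, n = 3) to -2.85 ± 0.66 (SD, n = 3), by 2.44 (SE 0.52, limma adjusted p = 0.0429). Contig123 was 1.51 above the controls (SE 0.41, adjusted p = 0.0579; 1.66 and 0.0465 with slide as a block), and Ealb_Met_P7_E8_T7_2175287 was 1.03 above (SE 0.42, adjusted p = 0.216). At the EC50 the 2 probes were 1.05 (SE 0.41, adjusted p = 0.505) and 0.60 (SE 0.42, adjusted p = 0.663) above the controls. In all, limma called 13 probes at the EC90, all higher, and 0 at the EC50, where 74 had an unadjusted p under 0.05. The EC90 count was 7 and the EC50 count 0 with slide as a block; within slide 2, P1_F7_T7_1328858 was 2.72 (adjusted p = 0.284) and P5_F2_T7_1329804 2.62 (adjusted p = 0.0647) above the controls, and within slide 1, with 1 exposed sample, they were 1.37 and 1.55 above. The EC90 count was 0 without control replicate 1, without control replicate 3 or without Zn EC90 replicate 1, it was 1 without Zn EC90 replicate 2 and 2 without replicate 3, and quantile normalization gave 34 (24 higher, 10 lower). With normexp and in a fit of only the groups compared limma gave 0 (144 at an unadjusted p under 0.05 in the fit of all groups). Without control sample 2-4 the counts were 160 (51 higher, 109 lower) at the EC90 and 76 at the EC50, and without Zn EC50 replicate 3 the latter was 1.

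After 4 days of zinc, P5_A12_T7_1330271, chosen after its values were seen, rose at the EC90 from -4.57 ± 0.45 (SD, n = 4) to -2.90 ± 0.37 (SD, n = 2), by 1.67 (SE 0.36, limma adjusted p = 0.0497). It was 1.41 above the controls with slide as a block (adjusted p = 1), the same as within slide 4 (1.41, adjusted p = 0.968). Contig123 was 0.75 above the controls at the EC50 (SE 0.39, adjusted p = 0.274) and 1.03 at the EC90 (SE 0.44, adjusted p = 0.409). The counts by limma were 1 at the EC90 and 0 at the EC50, where 177 probes had an unadjusted p under 0.05; with slide as a block both were 0. The EC90 count was 0 without control replicate 1 or 2 or Zn EC90 replicate 3, 2 without control replicate 3 and 17 without control replicate 4; the EC50 count was 59 without control replicate 4, 4 without replicate 3 and 12 after quantile normalization.

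After 8 days of zinc, Contig51 was at -3.74 ± 1.83 (SD, n = 2) at the EC90 against -0.15 ± 1.81 (SD, n = 4) in the controls, a difference of -3.59 (SE 0.86, adjusted p = 0.118). This difference was -5.48 with slide as a block (SE 0.95, limma adjusted p = 0.00238), the same as within slide 6. Of the controls only replicate 4 was on slide 6, so these values rest on 1 control and the spread comes from the other groups. Ealb_Met_P2_C10_SP6_2090305 was not well above background in the EC90 arrays and at least 2.42-fold higher in the controls (adjusted p = 0.118; 0.000416 with slide as a block, on the same 1 control). Contig123 differed by -0.09 at the EC50 (SE 0.44, adjusted p = 0.937) and 0.20 at the EC90 (SE 0.44, adjusted p = 0.886). By limma 0 probes were called at either concentration, with 38 (EC50) and 93 (EC90) at an unadjusted p under 0.05. With slide as a block the counts were 0 and 2, the 2 being Contig51 and Ealb_Met_P2_C10_SP6_2090305, and without control replicate 1 the EC90 count was 2.

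The series title sets cadmium against zinc, so the difference between the metals was tested on each day, averaging over the concentrations. On day 2, Contig123 was 14.6-fold higher under cadmium (log2 3.86, SE 0.29, limma adjusted p = 1.31e-11) and Ealb_Met_P7_E8_T7_2175287 14.2-fold higher (log2 3.83, SE 0.30, limma adjusted p = 1.31e-11). Both stayed called with slide as a block, at 3.25 (adjusted p = 1.99e-06) and 3.37 (adjusted p = 3.33e-07). The other calls of the 4, chosen after their values were seen, both higher under cadmium: Ealb_Met_P6_F11_SP6_2090590 (limma adjusted p = 2.27e-06), not well above background at the Zn EC50, and P3_D10_T7_1329721 (limma adjusted p = 0.000706), not well above background in any zinc array. A total of 5 probes were called with slide as a block (4 higher, 1 lower), and without Cd EC50 replicate 1 there were 55.

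On day 8 Contig123 was 19.7-fold higher under cadmium than under zinc (log2 4.30, SE 0.33, limma adjusted p = 1.54e-11) and Ealb_Met_P7_E8_T7_2175287 18.4-fold (log2 4.20, SE 0.33, limma adjusted p = 2.18e-11). With slide as a block these were 4.07 (adjusted p = 0.00752) and 4.27 (adjusted p = 0.00207). On day 8 all zinc arrays were on slide 6 and the cadmium arrays on slides 5 and 7, so no slide held both metals. The blocked values therefore rest on 1 control on slide 5 and 1 on slide 6. The other calls of the 5, chosen after their values were seen, were Ealb_Met_P6_F11_SP6_2090590 (2.12, adjusted p = 0.000501), Ealb_Met_P4_C4_SP6_2090061 (1.63, adjusted p = 0.00954) and Ealb_Pest_P5_A2_T7_2175153 (1.79, adjusted p = 0.00336). With slide as a block the count was 2 and these stood at 1.32, -0.11 and -0.09 (adjusted p = 0.997 each). Without Zn EC90 replicate 1 the count was 3.

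On day 4, limma called 346 of 909 probes between the metals, 210 higher and 136 lower under cadmium. Contig123 was higher by 3.70 (SE 0.33, limma adjusted p = 8.54e-10) and Ealb_Met_P7_E8_T7_2175287 by 3.28 (SE 0.33, limma adjusted p = 1.25e-08). Ealb_Met_P3_A4_T7_2175231, saturated on every cadmium array of the day, was at least 76.2-fold higher (limma adjusted p = 8.83e-05). Ealb_Met_P3_F12_SP6_2090417 was higher too (limma adjusted p = 0.000204). It was at 4.65 ± 1.22 (SD, n = 3) at the Cd EC90 and -5.02 ± 0.89 (SD, n = 2) at the Zn EC90, and at -5.32 ± 0.41 (SD, n = 3) at the Zn EC50, while the 2 samples of the Cd EC50 lay far apart, at -0.86 and, saturated, at 6.83. On the lower side were Ealb_Pest_P9_F6_SP6_2091032, at -2.81 (SE 0.99, limma adjusted p = 0.025), and Contig51, at -2.73 (SE 0.64, limma adjusted p = 0.00151). On that day all zinc arrays were on slide 4 and the cadmium arrays on slides 3 and 6, while the controls were on slides 3 and 4. A fit with slide as a block left 2 calls, Contig123 at 3.31 (adjusted p = 0.00531) and Ealb_Met_P7_E8_T7_2175287 at 3.68 (adjusted p = 0.000548). In that fit Ealb_Pest_P9_F6_SP6_2091032 was at -0.07 (adjusted p = 1) and Contig51 at -2.46 (adjusted p = 0.65), while with saturated spots at their value Ealb_Met_P3_A4_T7_2175231 went from 6.25 (SE 1.08) to 6.54 (SE 2.14, adjusted p = 0.434) and Ealb_Met_P3_F12_SP6_2090417 from 8.99 (SE 1.72) to 6.38 (SE 3.17, adjusted p = 1). For Ealb_Met_P3_A4_T7_2175231 the error widened, but its saturated cadmium and control readings do not show whether the difference changed. The call of Ealb_Met_P3_F12_SP6_2090417 ended through a wider error and a smaller difference as measured. No slide of day 4 held both metals, so within-slide values could not be had. Quantile normalization gave 147 higher and 203 lower, normexp 442 higher and 58 lower, and without Cd EC50 replicate 3 the count was 154. The call of Ealb_Pest_P9_F6_SP6_2091032 was lost without Cd EC50 replicate 3 (adjusted p = 0.117), Cd EC90 replicate 1 (0.0533), Zn EC50 replicate 2 (0.093) or Zn EC90 sample 1-2 (0.0945) and with normexp (0.0848), as was that of Contig51 with normexp (0.0665).

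**Figure D2:**
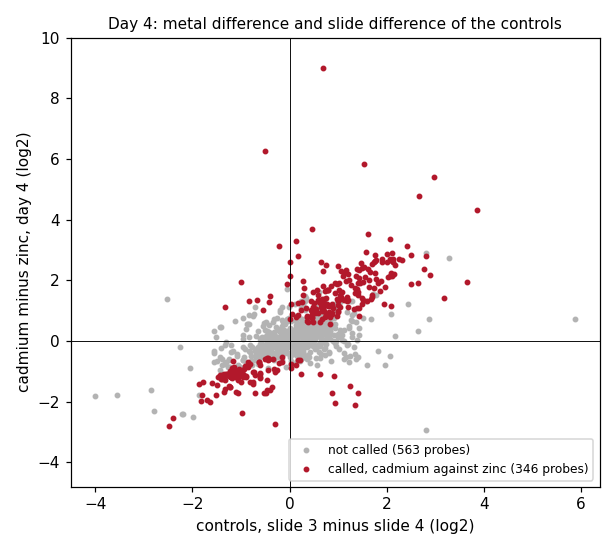
Day 4 difference between cadmium and zinc samples (vertical axis, log2) against the difference between the control samples of slide 3 and slide 4 (horizontal axis, log2), with 1 point per probe. Of the 346 probes called between the metals, shown in red, 323 differed the same way between the control samples.

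The EC50 and EC90 were compared within each metal over the 3 days. Under cadmium the EC90 exceeded the EC50 by 3.72 for Ealb_Met_P7_E8_T7_2175287 (SE 0.25, limma adjusted p = 6.52e-13), which is 13.2-fold, and by 3.36 for Contig123 (SE 0.25, limma adjusted p = 3.56e-12), which is 10.3-fold. With slide as a block these were 3.42 (adjusted p = 5.13e-10) and 3.35 (adjusted p = 2.87e-09). Of the 4 calls the others, chosen after their values were seen, were Ealb_Met_P6_F11_SP6_2090590 (2.58, SE 0.28, limma adjusted p = 3.51e-08) and P3_5C_T7_1329684 (0.81, SE 0.19, limma adjusted p = 0.0395; 0.53, SE 0.20 and 0.462 with slide as a block, which called 3). Without Cd EC50 sample 1-2 of day 4 there were 20 calls. Under zinc limma called 0 probes between the concentrations, with 10 at an unadjusted p under 0.05 and 0 with slide as a block. The zinc difference of Contig123 was 0.34 (95% interval -0.20 to 0.88), and that of Ealb_Met_P7_E8_T7_2175287 was 0.37 (95% interval -0.18 to 0.92).

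The response of Contig123 to cadmium on day 8 differed from that on day 2 by -0.79 (95% interval -1.78 to 0.19, adjusted p = 0.802), and that of Ealb_Met_P7_E8_T7_2175287 by -0.23 (95% interval -1.23 to 0.77, adjusted p = 0.879). For cadmium limma called 0 probes, with 48 at an unadjusted p under 0.05 and 0 with slide as a block; without control replicate 1 of day 8 there was 1. For zinc the 1 call was Ealb_Met_P4_G7_SP6_2090089, whose response fell by 2.85 between the days (SE 0.61, limma adjusted p = 0.0455); with slide as a block the difference was as large and its error wider (-2.89, SE 0.84, adjusted p = 0.999). It was chosen after its values were seen. In control soil it rose from -5.35 ± 0.71 (SD, n = 3) to -3.44 ± 0.24 (SD, n = 4), by 1.91 (limma F-test over the 3 days, adjusted p = 0.013), while its means went from -5.00 to -5.36 at the Zn EC50 and from -3.47 to -5.00 at the Zn EC90, so the larger part of the difference lies in the controls. The call was lost when any of 14 of the 17 samples was left out in turn, so that the count was then 0, and 56 probes had an unadjusted p under 0.05.

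In control soil, Contig51 rose over time, from -4.89 ± 1.04 (SD, n = 3) on day 2 to -3.12 ± 0.31 (SD, n = 4) on day 4 and -0.15 ± 1.81 (SD, n = 4) on day 8 (limma F-test, adjusted p = 0.000724). Ealb_Met_P2_C10_SP6_2090305 was not well above background in the 4 control arrays of day 4 and was measured in 1 of day 2 and 3 of day 8 (limma adjusted p = 0.000627). In all, 73 probes differed between the control days; day 4 lay above day 2 for 11 and below it for 62, and day 8 lay above for 16 and below for 57. Day and slide cannot be told apart in the controls, because no slide held controls of different days. The count was 5 without day 2 replicate 1, 4 without day 2 replicate 3, 269 without day 2 sample 2-4, 138 without day 4 replicate 2, 14 without day 4 replicate 4 and 44 without day 8 replicate 1; normexp gave 4, and a fit of the control groups alone gave 0.

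Calls shared by cadmium and zinc were counted at the same concentration and day. By limma 0 probes were called under both metals in any of the 6 pairs. Independent lists would share 0.0429 at the EC90 of day 2 and 0.0033 at the EC90 of day 4. In the other pairs zinc had 0 calls, so none could be shared. The absence of shared calls therefore does not show separate responses. The shared count over the pairs was 3 with slide as a block, with normexp 1, after quantile normalization 3, and without control sample 2-4 of day 2 it was 104. It was 3 without control replicate 4 of day 4 and 2 without control replicate 1 of day 8. It was 1 without Cd EC50 replicate 1, Cd EC90 replicate 1 or Cd EC90 replicate 3 of day 2, Zn EC90 sample 1-2 or replicate 3 of day 4, or Cd EC50 replicate 2 or 3 of day 8. Over all probes, which are not independent replicates, the correlation of the cadmium and zinc differences was 0.537 (EC50) and 0.362 (EC90) on day 2, against 0.448 and 0.484 for simulated unchanged groups with the same controls. On day 4 it was -0.506 and -0.30 against 0.365 and 0.353, and on day 8 it was 0.31 and 0.34 against 0.415 and 0.352. The covariances were 0.278 and 0.231 on day 2 (simulated 0.144 and 0.158, SD between draws 0.0948 and 0.0933). On day 4 they were -0.354 and -0.132 (simulated 0.114 and 0.118, SD 0.0834 and 0.0923). On day 8 they were 0.114 and 0.138 (simulated 0.135 and 0.111, SD 0.0878 and 0.0817). With a separate pair of controls for each metal, the mean correlation was -0.557 and -0.411 on day 4 and 0.0511 and 0.0802 on day 8. Neither the simulation nor these splits take the slide into account, and on day 4 a slide difference moves the metals in opposite directions from controls that lie on both slides. With slide as a block the correlations were 0.0198 and -0.149 on day 4, 0.255 and 0.366 on day 2, and -0.123 and 0.0227 on day 8. Day 2, with 3 control samples, could not be split, so part of any excess there may come from the shared controls.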

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

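The tests of the slide and of a different action of the metals on day 4, of measurement noise in the variable probes, of a cadmium sample under a control label, of array brightness as the whole separation and of the distances of the day 2 controls from other groups were chosen only after the result was seen.

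Between cadmium and zinc on day 4, 346 probes differed, against 4 on day 2 and 5 on day 8. On day 8 the metals lay on separate slides too. The control samples of slide 3, which held cadmium arrays, differed from those of slide 4, which held all zinc arrays, in the direction of the metals for 93.4% of the 346 (76.3% of all probes), by a median of 1.01 in that direction. The array brightness is part of the same split (mean log2 75th percentile 9.83 under cadmium and 11.1 under zinc), and slopes on brightness from days 2 and 8 had r = -0.52 over probes with the metal difference, so slide and brightness cannot be told apart there. A different action of cadmium and zinc on most of these probes is argued against. With slide as a block the called probes kept a median of 10.8% of their difference (median 1.29 before and 0.15 after, median SE 0.36 and 0.64). The calls ended through smaller differences and wider errors both. No slide of day 4 held both metals, so the 10.8% and the 93.4% rest largely on the same controls, 2 on each slide. They are therefore not separate support. Contig123 and Ealb_Met_P7_E8_T7_2175287 were called in that fit too, and 1 of 100 splits, the real one, called as many as 346 (highest other 252), so chance is excluded, as it would be for a slide difference.

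The day 2 control sample 2-4 stood apart from control replicates 1 and 3: root mean square differences were 1.41 and 1.39 log2 units, against 0.77 between replicates 1 and 3 and a median of 0.95 over 43 pairs within groups. A cadmium sample under a control label is argued against, since Contig123 in the sample (-3.68) lay 1.86 below the lowest cadmium sample of day 2. A zinc sample under a control label was not tested and stays open. By root mean square difference the nearest samples were Zn EC90 replicate 1 of day 2 (0.847), control replicate 1 of day 8 (0.85) and Zn EC50 replicate 2 of day 2 (0.85). To weigh array brightness as the whole separation, the sample's own arrays, on slides 1 and 2, were compared. They were 0.55 log2 units apart in brightness with a root mean square difference of 0.158, while array 4 and replicate 3 were 0.625 apart with 1.38. The sample's arrays were paired for their small differences, so the 0.158 was held low by that choice and does not decide the question. Brightness stays open (over probes, r = 0.206 with slopes on brightness from days 4 and 8). Of the 40 samples of other groups, 38 were nearer to sample 2-4 than its fellow controls were, and the median difference from them was 1.01 for sample 2-4, 1.33 for replicate 1 and 1.38 for replicate 3, so which controls are typical of day 2 is not settled. Differences between the pools of worms stay open and were not tested.

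In 20 probes the samples of a group differed widely, with residual SDs of 1.63 to 3.85. For the 9 probes that were not used to find the near-identical pairs and were measured in them, noise within these pairs was small. Their 32 differences had a median of 0.109 log2 units (quartiles 0.0529 and 0.225, largest 0.985), against 1.93 between other samples of a group over the 20 probes. The 1.93 also holds readings that were saturated or not well above background, which the 32 leave out. The pairs were picked for small differences over other probes, so larger noise between other arrays stays open. For the 10 probes used to find the pairs the median of 0.0647 was fixed by that choice and leaves noise open. Slide is argued against: it explained a median of 16.7% of their variance within groups, less than the 34.2% over all probes. No biological explanation was tested.

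Among the control samples of day 8, P1_F7_T7_1328858 had replicate 4 at -0.72 and the others at -0.09 to 0.03 (gap over range 0.843). Ealb_Met_P3_A4_T7_2175231 had replicate 2 at 0.94 and the others at 4.71 to 4.88 (0.956), but those 3 were saturated, which narrows their range, so the ratio says nothing about the size of the gap. P5_A12_T7_1330271 had replicate 3 at -4.67 and the others at -4.21 (0.988). These are 3 of 34 control groups tested, and chance gives about 1 in 20. The difference between the zinc responses of day 8 and day 2 was called for 1 probe.

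Other splits of the same samples were refitted for each count. On day 2 there were 10 splits, too few for a share under 0.05: the Cd EC50 gave 2 calls (highest other 263, 2 splits as large), the Cd EC90 3 (161, 2 splits), the Zn EC90 13 (106, 3 splits) and the Zn EC50 0 by limma with 74 at an unadjusted p under 0.05 (197, 10 splits). The splits that called most put control replicates 1 and 3 together, which points to a structure of the samples. Of 35 splits, 3 gave as many as the 3 calls of the Cd EC90 of day 4 (highest other 3), 2 as many as the 2 of the Cd EC50 of day 8 (11) and 2 as many as the 6 of the Cd EC90 of day 8 (6), so chance was not excluded for these counts. For the Zn EC50 of day 4 limma called 0, with 177 at an unadjusted p under 0.05; the highest other split called 77. The 2 other splits as large for the Cd EC90 of day 4 keep the cadmium samples together, as does the 1 other for the Cd EC50 of day 8. Such splits still set the cadmium samples against controls, so they do not show that chance gives as many calls.

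For the comparisons over more samples 100 splits were refitted. Between the metals on days 4 and 8 these were all the splits possible within concentrations, and elsewhere they were drawn at random. Chance was not excluded for cadmium against zinc on day 2 (4 calls, 12 splits as large, highest other 79) and day 8 (5 calls, 5 splits, 19). It was not excluded for the change of the zinc response over time (1 call, 9 splits, 92). Where the real count is 0, every split is as large and the comparison tests nothing, as for the Zn EC50 of day 2 (10 splits) and day 4 (35 splits). The same holds for the zinc concentrations (0 by limma, 10 at an unadjusted p under 0.05, 100 splits, highest other 14) and the cadmium response over time (0 by limma, 48 at an unadjusted p under 0.05, 100 splits, highest other 100). The share was under 0.05 in the splits drawn for the cadmium concentrations (4 calls, 2 splits, highest other 41) and for the control days (73 calls, 1 split, highest other 67), where day and slide are confounded. For both it changed with the random draw, to either side of that limit, so chance is not taken as excluded. Splits calling several times the real count again point to a structure of the samples.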

How the results depend on the processing

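The fits of 48 separate arrays and of all spots were chosen only after the result was seen. Of 456 values under alternatives of the probes the naming rule gives, 409 kept their side of the threshold and direction, 47 lost the call (22 without 1 sample, 25 under other settings) and 0 reversed direction. These do not cover the probes chosen after their values were seen, of which Ealb_Met_P4_C4_SP6_2090061 and Ealb_Pest_P5_A2_T7_2175153 turned direction between the metals of day 8 with slide as a block (1.63 to -0.11 and 1.79 to -0.09). Over all alternatives, leaving out samples included, the effect of Contig123 at the Cd EC90 lay between 5.69 and 7.41 on day 2. It lay between 5.51 and 6.34 on day 4 and between 5.64 and 6.295 on day 8. Where counts moved, the cause was not tested. Counts of 0 are by limma, and the counts at an unadjusted p under 0.05 in the fit first given were 144 for the Zn EC90 of day 2, 210 for the Cd EC50 of day 4, 92 for the Zn EC90 of day 4, 56 for the zinc response over time and 266 for the control days.

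Quantile normalization gave 13 calls for the Cd EC50 of day 2, 5 for the Cd EC90 of day 2, 34 for the Zn EC90 of day 2, 87 for the Cd EC50 of day 4, 12 for the Zn EC50 of day 4 (4 higher, 8 lower), 4 for the Zn EC90 of day 4 (1 higher, 3 lower), 2 for the zinc response over time and 3 shared calls. The Cd EC90 of day 8 had 3 higher and 1 lower.

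With normexp background correction limma gave 0 calls for the Zn EC90 of day 2 (144 at an unadjusted p under 0.05 without it), 0 for the Zn EC90 of day 4 and 0 for the zinc response over time. It gave 3 for the Cd EC90 of day 8, 1 for the Zn EC90 of day 8, 2 for the metals of day 8, 4 for the control days and 1 shared call.

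With no filter on dim probes limma gave 5 calls for the Zn EC90 of day 2, and 0 for the Zn EC90 of day 4 (92 at an unadjusted p under 0.05 with the filter) and for the zinc response over time.

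With slide as a block (slide block) the counts were 4 for the Cd EC50 of day 2, 7 for the Zn EC90 of day 2, 1 for the Cd EC50 of day 8, 3 for the Cd EC90 of day 8, 2 for the Zn EC90 of day 8, 2 for the metals of day 4, 2 for the metals of day 8 and 3 shared calls. By limma they were 0 for the Zn EC90 of day 4 and for the zinc response over time (56 at an unadjusted p under 0.05 without the block). The control days could not be fitted with it.

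The replicate numbers do not pair the samples: of 57 pairs with the same number 21 had r over 0.1, the median r was -0.0857 (-0.503 to 0.682), and 11 of 43 samples correlated best with one of their own number. With replicate number as a block (replicate block) the counts were 4 for the Cd EC50 of day 2, 1 for the Cd EC50 of day 4, 58 for the Zn EC50 of day 4, 7 for the Zn EC90 of day 4 and, by limma, 0 for the zinc response over time (56 at an unadjusted p under 0.05 without the block).

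The estimation of array weights stopped before it converged, so its counts are uncertain. With array weights the counts were 368 (Cd EC50), 406 (Cd EC90), 214 (Zn EC50) and 341 (Zn EC90) on day 2, 6 for the Zn EC50 of day 4, 172 for the metals of day 2, 11 for the metals of day 8, 168 for the cadmium and 139 for the zinc response over time, 332 for the control days and 390 shared calls. By limma they were 0 for the Cd EC50 and the Zn EC90 of day 4 (210 and 92 at an unadjusted p under 0.05 without weights).

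In a fit of only the groups compared the counts were 5 for the Cd EC50 of day 2, 1 for the Zn EC50 of day 2, 14 for the metals of day 2 and 2 for the zinc response over time. By limma they were 0 for the Zn EC90 of day 2, the Cd EC50 of day 4, the Zn EC90 of day 4 and the control days (144, 210, 92 and 266 at an unadjusted p under 0.05 in the fit of all groups). Shared calls were not run with it.

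With 48 arrays as separate samples the counts were 8 for the Cd EC50 of day 2, 11 for the Cd EC90 of day 2, 1 for the Zn EC50 of day 2, 16 for the Zn EC90 of day 4, 2 for the Zn EC90 of day 8, 7 for the cadmium concentrations and 5 shared calls. With all spots kept there were 6 for the Cd EC50 of day 2 and 1 shared call.

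Leaving out each sample in turn gave 2 to 99 calls for the Cd EC50 of day 2, 3 to 107 for the Cd EC90 of day 2, 0 to 76 for the Zn EC50 of day 2 and 0 to 160 for the Zn EC90 of day 2, each highest without control sample 2-4. It gave 1 to 175 for the Cd EC50, 3 to 3 for the Cd EC90, 0 to 59 for the Zn EC50 and 0 to 17 for the Zn EC90 of day 4. On day 8 it gave 2 to 11 for the Cd EC50, 4 to 5 for the Cd EC90, 0 to 0 for the Zn EC50 and 0 to 2 for the Zn EC90. For the metals it gave 4 to 55 on day 2, 154 to 411 on day 4 and 3 to 5 on day 8. It gave 3 to 20 for the cadmium and 0 to 0 for the zinc concentrations, 0 to 1 for the cadmium and 0 to 1 for the zinc response over time, 4 to 269 for the control days and 0 to 104 shared calls. Counts of 0 are by limma, with 74, 177, 38 and 93 at an unadjusted p under 0.05 in the full fit for the Zn EC50 of days 2, 4 and 8 and the Zn EC90 of day 8, and 10 and 48 for the zinc concentrations and the cadmium response over time.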

Other observations

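The tests of these observations were planned, except the correlation without the Cd EC50 of day 4, which was chosen only after the result was seen.

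Contig123 and Ealb_Met_P7_E8_T7_2175287 moved together beyond the group means. Over 43 samples their deviations from the group means had r = 0.788 and rho 0.846. The permutation p was 1e-05 for each, the smallest 100000 permutations can give. Without the 2 farthest samples r was 0.758. The shuffling took the deviations as independent, but those of a group are tied by their mean. Slide also explained a median of 34.2% of the variance within groups over all probes. The p-value may therefore be too small, and how strongly other probes correlate with these 2 was not examined. That both probes report 1 transcript may hold but stays open, since the limit set was not reached; without the Cd EC50 of day 4 r was 0.906. In that group Contig123 read -0.80 and -1.07, while Ealb_Met_P7_E8_T7_2175287 read -0.65 and -2.81. The probe sequences were not compared.

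Probes named Ealb_Met were called in at least 1 exposure in 9 of 305 cases (2.95%), other probes in 11 of 604 (1.82%), with an odds ratio of 1.64 (95% interval 0.593 to 4.4, Fisher p = 0.338). The interval leaves open whether this class responds more often.

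P1_B6_T7_1328848 reached 3.57 and was well above background on 22 of the 48 arrays. Ealb_Pest_P7_C2_SP6_2092135 and Ealb_Pest_P6_H1_SP6_2092020 each ranged over 6.80 log2 units, and their deviations from the group means correlated with r = 0.999938. Of the 190 pairs among the 20 most variable probes, 22 had r over 0.9 for these deviations.

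Contig51 was higher on day 8 than on day 2 in control soil (-0.15 against -4.89), and its means were higher on day 8 in the other groups too: -1.82 against -4.77 at the Cd EC50, -3.21 against -6.33 at the Cd EC90, -0.96 against -6.20 at the Zn EC50 and -3.74 against -5.27 at the Zn EC90. The differences between days in the exposed groups were not tested.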
